A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

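The series holds 8 samples in 8 groups, 1 library each: HEK and MEF cells, each uninduced, with dox, with ponA and with both. Groups were taken from the sample titles. Libraries were directional, from rRNA-depleted total RNA, and were read as 76 nt pairs, per the labels' protocols. Reads were aligned with STAR 2.7.5c to hg38 and mm10, per the submitters' processing notes. The files are 6 tables of skipped exons with rMATS column names, per the file headers, each setting 1 treated library against the uninduced library of its line. The rMATS version, its annotation and its settings are not given in the sources used here. Per the file headers, the authors' tables give read counts of inclusion and skipping from junctions plus exon bodies, an inclusion level as a fraction, and a p-value with an FDR for each event. Each cell holds 1 library, so the deposited FDR compares 2 libraries. The uninduced columns were identical in 100% of the events that tables of one line share, so the 3 comparisons of a line share 1 control. Every event in the tables has at least 1 inclusion and 1 skipping read over its pair of libraries, so exons never skipped are not in them. Inclusion levels recomputed from the deposited counts and effective lengths were within 0.0005 of the deposited ones.

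Gene symbols were taken from the tables. Of 21760 mouse exons with a symbol in a GRCm38 gene table, 99.7% lay inside that gene's bounds. No genome sequence was used here, so the planned motif comparison was not run. How reads enter the tables could affect the values. Exon-body reads weight long exons heavily, reads covering several events are counted in each, and genes with near-identical copies can share reads.

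PSI was computed as inclusion reads over effective length, divided by the sum of that value and the same value for skipping reads. Its 95% Wilson interval was computed on reads and carried to the PSI scale. An exon was measured with at least 20 reads in both libraries and called with a deposited FDR under 0.05 and a PSI difference of at least 0.1. Of events that share an exon, the one with the most reads was kept. Alternatives were at least 10 or 50 reads, no minimum, differences of 0.05 or 0.2, an FDR of 0.01, Fisher's exact test with Benjamini-Hochberg adjustment, a chi-square test divided by its inflation, PSI without length normalisation, and every event counted. Inflation of the chi-square values was 2.05 to 2.32.

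For each line, exons called with both single drugs were counted among exons measured in 3 libraries. The count was set beside n1 × n2 / N per direction and beside 100 simulations of unchanged libraries with the PSI of the uninduced one, called with Fisher's exact test. The retained dox effect is the median signed difference between the libraries with both drugs and with ponA, over the median signed difference between the dox and uninduced libraries. Its 95% interval came from 10000 resamples of exons, and 1000 simulations had effects that add on the logit scale. The joint effect of both drugs was divided by the sum of the single effects in the same way, for same-direction and opposite-direction exons apart. For the second set this sum is near 0. Alternatives were the logit scale with 0.5 reads added, exons with an uninduced PSI of 0.2 to 0.8, exons chosen by the difference between ponA and both drugs, and, added after the data were seen, 50 random equal splits of the uninduced, dox and ponA reads, with exons chosen on one part and measured on the other. Human and mouse exons were matched by symbol and length where that pair was unique in both species, with flanking exon lengths as an alternative. A Fisher p-value across exons had been planned for these and is not printed, because exons are not replicates. The odds ratio is given in its place.

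Named exons were fixed by rule before the data were examined. The rule took the 10 largest rises and 10 largest falls per comparison with 1 exon per gene, the largest changes of each gene list, the 6 exons per direction with the largest smaller-of-both effect for both drugs, and the 8 largest for orthologs. The 8 gene lists were MBNL targets, RBFOX targets, splicing regulators, cytoskeleton and adhesion, membrane traffic, transcription and chromatin, muscle excitation and contraction, and genes with epithelial or mesenchymal splicing. A list's count takes all measured exons of its genes. MBNL1 itself is in the lists of MBNL targets and splicing regulators, and with dox its transgene reads can enter these counts. Each list's called exons were compared with 10000 random lists matched in 10 bins of read depth, and a list is said to be inside the range of random lists where its count did not exceed the upper bound of their central 95% range. Random lists were not matched on PSI and were drawn exon by exon. Genes listed for their alternative exons can exceed them for that reason alone. Within a gene list, examples already named were passed over for the next largest. A few exons that the rule selected are not reported here. The exons called in opposite directions in the lines are all named in the closing section.

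The calling code was tested on simulated data for HEK dox with 40632 exons, 200 of them changed. With Fisher's exact test it recovered 14% of exons with a true difference of 0.1, 52% at 0.2, 66% at 0.3 and 90% at 0.5, with 2 false calls among 40432. A true retained effect of 0.5 was measured as 0.489 on 32049 exons. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.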

Results

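Splicing was measured in 8 RNA-seq libraries, 4 from a human embryonic kidney line (HEK) and 4 from mouse embryonic fibroblasts (MEF). Both lines carry a pair of inducible transgenes. Doxycycline (dox) switches on tagged MBNL1, the splicing regulator that is sequestered by repeat RNA in myotonic dystrophy. Ponasterone A (ponA), an insect steroid, switches on RBFOX1 fused to mOrange, RBFOX1 being a splicing regulator of neurons and muscle. In each line 1 library came from uninduced cells, 1 from cells given dox, 1 from cells given ponA and 1 from cells given both. Ribosomal RNA was depleted, cells were harvested 24 h after drug addition, and fragments were read from both ends at 76 nt. MEF cells received dox at 1000 ng/mL. For HEK cells the labels conflict, since the treatment entries and protocol give 10 ng/mL and the sample titles give 1000. PonA was given at 10 µM per the protocol, while the sample titles give 1 with no unit. The source name of all 8 samples reads embryonic kidney, and the MEF samples were taken as fibroblasts from their titles and protocol. The series title names the questions: whether MBNL1 and RBFOX1 regulate the same exons, whether one buffers the other, and whether this is conserved.

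The authors' deposited tables gave inclusion and skipping reads of cassette exons in 1 treated library and the uninduced library of its line. Inclusion is given as PSI, the length-normalised fraction of transcripts that contain the exon. An exon was called where the false discovery rate (FDR) in the authors' deposited table was under 0.05, PSI differed by at least 0.1 and both libraries held at least 20 reads. Among measured exons the HEK tables held 15921043 to 17360003 uninduced reads and 12111679 to 14374944 treated reads. The MEF tables held 8609701 to 10193169 uninduced reads and 8597776 to 10589133 treated reads. These totals count a read once for every event it touches and are not library depths. The median exon had 173 to 180 reads in the HEK uninduced library and 207 to 219 in the MEF one. No group had a replicate, so no difference has a replicate check, and each call compares 2 libraries rather than 2 conditions. Brackets after a PSI hold its 95% Wilson interval, which covers counting error only, because reads are not independent molecules. Exon positions are 1-based, in hg38 for HEK and mm10 for MEF. Every named exon was counted as a cassette exon in the authors' deposited data, which does not exclude that it is mutually exclusive with another exon. Whether a named exon lies in coding sequence or in a UTR was not analysed here.

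MBNL1 reads were higher in each library labelled with dox. In HEK, inclusion reads of MBNL1 events, as a share of the table's reads, were 3.97 times those of the uninduced library with dox and 5.17 times with both drugs, against 0.908 with ponA alone. Each table holds its own set of MBNL1 events, and on the 5 found in all HEK tables the ratios were 6.07, 8.22 and 0.880. In MEF the ratios were 2.12 with dox, 1.79 with both drugs and 1.27 with ponA alone, and 1.88, 1.67 and 1.0 on the 6 events found in all tables. RBFOX1 reads were higher in each ponA library where they could be read. In MEF they were 9.53 times the uninduced level with ponA and 8.89 times with both drugs, against 1.1 with dox. In HEK the single RBFOX1 event of the ponA table had 5 inclusion reads in the uninduced library and 1999 in the ponA library. The other HEK tables held no RBFOX1 event, so the HEK library with both drugs has no such check. Inclusion reads of events in RBFOX2, a paralog of RBFOX1, were 0.472 times the uninduced share with ponA (11 events) in HEK. With both drugs they were 0.835 times (17 events), and in MEF 0.978 and 0.97 times. Inclusion reads also fall when an exon is skipped more, and the events differ between these comparisons. The RBFOX2 ratios therefore do not measure its transcript level. A cDNA transgene gives reads only in the exons it carries, so the MBNL1 and RBFOX1 ratios check the labels and do not measure protein. For the same reason the PSI of an MBNL1 exon in a library with dox mixes transgene and endogenous reads and is no measure of endogenous splicing alone.

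**Figure D1:**
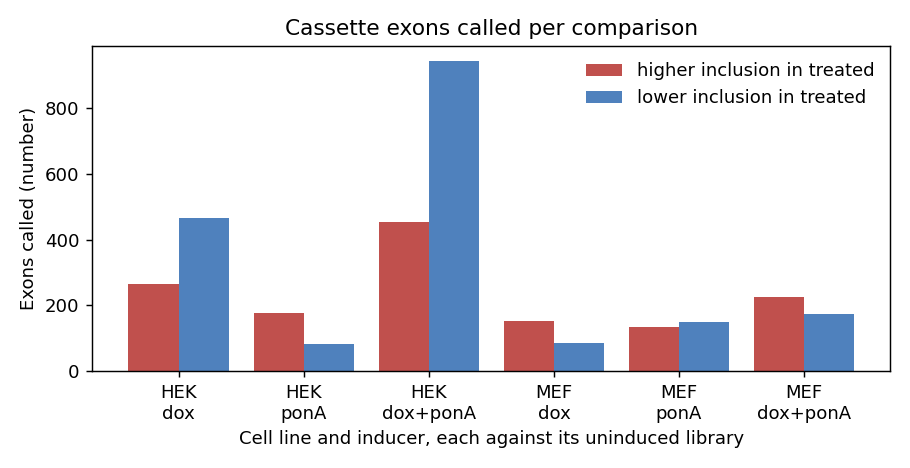
Number of cassette exons called higher (red) or lower (blue) in each treated library than in the uninduced library of its line, 1 library per group. The HEK library with both drugs has the most calls, 452 higher and 941 lower.

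Dox in HEK moved exons of cytoskeletal and membrane traffic genes in both directions. The 48 nt exon of CLASP1, a microtubule plus-end protein (chromosome 2, 121445449 to 121445496), rose from 0.142 (0.0874 to 0.222) to 0.883 (0.770 to 0.944). The 42 nt exon of ARFGAP2, a regulator of ARF1 in Golgi transport (chromosome 11, 47172710 to 47172751), rose from 0.0539 (0.0209 to 0.132) to 0.762 (0.641 to 0.852). The 156 nt exon of SYNE1, which links the nucleus to the cytoskeleton (chromosome 6, 152368972 to 152369127), fell from 0.925 (0.681 to 0.986) to 0.115 (0.0552 to 0.224). In PTCH1, the Hedgehog receptor, a 156 nt exon fell from 0.879 to 0.235. Other large rises were in THOC5, an mRNA export factor (0.0309 to 0.725), the Wnt transcription factor LEF1 (0.102 to 0.795), the junction protein AFDN (0.218 to 0.891), ARAP1 (0.0675 to 0.747) and the kinase MAP2K7 (0.169 to 0.799). Other large falls were in TTC28 (0.919 to 0.118), FAM122B (0.925 to 0.138), the glucose transporter SLC2A8 (0.892 to 0.216), MFSD13A (1 to 0.324), ARHGAP17 (0.841 to 0.231) and MAPK12 (1 to 0.402).

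Of 40632 exons measured with dox in HEK, 731 were called in 580 genes, 266 higher and 465 lower. On unnormalised read shares the split was 259 higher and 304 lower. Among exons of at most 75 nt, a limit chosen after the data were seen, it turned to 92 higher and 74 lower. Of the 465 lower exons, 301 had a PSI of at least 0.95 in uninduced cells. Known MBNL target genes had 30 of 282 measured exons called, 17 higher and 13 lower, where depth-matched random lists had a median of 5. These random lists were not matched on PSI, and lists not chosen for MBNL exceeded them as well. An excess over them, here and below, therefore does not show that targets of 1 regulator were singled out. Among them the 36 nt exon of INSR, the insulin receptor, rose from 0.166 to 0.772, the 12 nt exon of the Hippo transcription factor TEAD1 rose from 0.194 to 0.795, and a 95 nt exon of MBNL2 fell from 0.649 to 0.0651. RBFOX target genes had 18 of 246 exons called, 11 higher and 7 lower, among them the 795 nt exon of the actin regulator ENAH (0.760 to 0.187). Cytoskeleton and adhesion genes had 37 of 408 called, 25 higher and 12 lower, including PPFIBP1 (0.278 to 0.881) and MACF1 (0.111 to 0.684). Genes with known epithelial or mesenchymal splicing had 19 of 151 exons called, 7 higher and 12 lower, such as STX2 (0.819 to 0.289) and TJP1 (0.163 to 0.677). Membrane traffic genes had 11 of 283 called, 6 higher and 5 lower, including VPS39 (0 to 0.564). The remaining 3 lists stayed inside the range of random lists: splicing regulators with 6 of 302 exons, transcription and chromatin genes with 7 of 312, and muscle genes with 3 of 66. The FDR of the authors' deposited table was 0.0036 for a 615 nt KANK1 exon (0.303 to 1), which no longer passed with Fisher's exact test. After chi-square values were divided by their inflation, KANK1, ITGA7, FRMD5, ARHGAP4 and HERC2P9 no longer passed and 197 exons were called. HERC2P9 is a pseudogene that can share reads with HERC2, so its fall from 0.90 to 0.236 is uncertain.

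Dox in MEF also moved exons of cytoskeletal and membrane traffic genes. The 42 nt exon of Numa1, a spindle protein (chromosome 7, 102002295 to 102002336), rose from 0.0192 (0.00818 to 0.0443) to 0.864 (0.807 to 0.906). The 45 nt exon of Tbc1d23 (chromosome 16, 57181492 to 57181536) rose from 0.0376 (0.0127 to 0.106) to 0.915 (0.818 to 0.963). The 54 nt exon of Mbnl1 itself (chromosome 3, 60614683 to 60614736) was at 0.970 (0.937 to 0.986) uninduced and 0.232 (0.198 to 0.269) with dox, where transgene reads can lower it. The 96 nt exon of Add3, an adducin of the membrane skeleton (chromosome 19, 53244310 to 53244405), fell from 0.97 (0.913 to 0.993) to 0.165 (0.116 to 0.230). Rises were also called in Apbb2 (0.134 to 0.976), the centrosomal gene Pcnt (0.0799 to 0.896), the reelin receptor Lrp8 (0.185 to 1), the formin Inf2 (0.0923 to 0.874), Baz2b (0.0755 to 0.845), Tead1 (0.00895 to 0.747), the lysyl hydroxylase Plod2 (0.190 to 0.910) and Mta1 (0.260 to 0.966). Falls were called in the exocyst gene Exoc1 (0.928 to 0.229), Rragb (0.885 to 0.199), the Notch regulator Numb (0.815 to 0.173), Fryl (0.677 to 0.0427), Gpr137 (1 to 0.483) and the metalloprotease Adam15 (0.630 to 0.134).

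Of 20075 exons measured with dox in MEF, 238 were called in 207 genes, 153 higher and 85 lower. Their lengths were a multiple of 3 nt in 78.6% of called exons and 41% of uncalled exons. MBNL target genes had 24 of 202 exons called, 14 higher and 10 lower, against a median of 2 in depth-matched random lists. RBFOX target genes had 16 of 151 called, 10 higher and 6 lower, among them Clstn1 (0.157 to 0.613). Cytoskeleton and adhesion genes had 27 of 297 called, 20 higher and 7 lower, with Itga6 at 0.0199 and 0.708 and Syne1 at 0.0231 and 0.693. Membrane traffic genes had 11 of 147 called, 6 higher and 5 lower, with Dnm2 (0.0364 to 0.562), Spag9 (0.0189 to 0.459) and the clathrin adaptor Picalm (0.0152 to 0.410). Transcription and chromatin genes had 12 of 187 called, 9 higher and 3 lower, including Nfya (0.381 to 0.720) and Foxm1 (0.719 to 0.994). Genes with epithelial or mesenchymal splicing had 8 of 98 exons called, 5 higher and 3 lower, with Kif13a at 0 and 0.436. Muscle genes had 3 of 44 called, with Tpm1 at 0.507 and 0.141. Splicing regulators had 5 of 181 called, inside the range of random lists, with Mbnl2 at 0.987 and 0.551. With inflation removed, 140 exons were called, and Sfxn4 and Arhgap17 no longer passed.

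PonA in HEK raised more exons than it lowered, among them many in cytoskeletal genes. The 63 nt exon of MICAL3, which oxidises actin filaments (chromosome 22, 17826454 to 17826516), rose from 0.104 (0.0472 to 0.215) to 0.776 (0.626 to 0.878). The 36 nt exon of the protocadherin FAT1 (chromosome 4, 186590368 to 186590403) rose from 0.0146 (0.00401 to 0.0520) to 0.677 (0.581 to 0.761), and the 21 nt exon of the kinesin KIF21A rose from 0.0680 to 0.725. In TPM1, tropomyosin, 1 exon of 76 nt rose from 0.116 to 0.699 and another of 76 nt fell from 0.824 to 0.155. These lie at 63061713 to 63061788 and at 63061198 to 63061273 on chromosome 15. The 37 nt exon of ATP5F1C, the gamma subunit of ATP synthase (chromosome 10, 7806974 to 7807010), fell from 0.967 (0.953 to 0.977) to 0.462 (0.427 to 0.498). Rises were also called in the kinase genes MAST2 (0.121 to 0.761) and CAMKK2 (0.0146 to 0.631), in MDM1 (0.129 to 0.741), RANBP3 (0.359 to 1) and the myosin phosphatase partner MPRIP (0.143 to 0.732). Falls were called in the light chain MYL6 (0.831 to 0.201), SEPTIN6 (0.696 to 0.0857), SERP2 (0.858 to 0.331) and the chromatin remodeller PBRM1 (0.828 to 0.347).

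Of 40492 exons measured with ponA in HEK, 259 were called in 224 genes, 177 higher and 82 lower. RBFOX target genes had 12 of 256 exons called, 9 higher and 3 lower, against a median of 1 in depth-matched random lists, including PLOD2 (0.261 to 0.742) and CLSTN1 (0.205 to 0.683). MBNL target genes had 9 of 291 called, 7 higher and 2 lower, including ANK2 (0.130 to 0.691) and SPAG9 (0.189 to 0.695). Cytoskeleton and adhesion genes had 22 of 424 called, 19 higher and 3 lower, including the kinesin genes KIF23 (0.172 to 0.721) and KIF13A (0.508 to 0.958). Transcription and chromatin genes had 8 of 300 called, 7 higher and 1 lower, including NFYA (0.316 to 0.816) and TCF7L2 (0.423 to 0.893). Membrane traffic genes had 8 of 302, 4 in each direction, with SEC16A falling from 0.688 to 0.285. Muscle genes had 6 of 68, 4 higher and 2 lower, with CAMK2G rising from 0.0401 to 0.440. Genes with epithelial or mesenchymal splicing had 7 of 146, 2 higher and 5 lower, with STX2 falling from 0.819 to 0.407. Splicing regulators had 2 of 300, inside the range of random lists, with TRA2A at 0.190 and 0.331, and none passed at an FDR under 0.01 in the authors' deposited table. With Fisher's exact test CKMT2-AS1, SLFN12L, RNASEH1-AS1, NUDT17 and NUP62 no longer passed. With inflation removed 77 exons were called, and RANBP3, MDM1, MYL6, SEPTIN6 and SERP2 also failed.

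PonA in MEF moved exons of cytoskeletal genes and of 4 splicing regulators. A 224 nt exon of the phosphate carrier Slc25a3 (chromosome 10, 91122108 to 91122331) fell from 0.976 (0.879 to 0.996) to 0.305 (0.250 to 0.366). The 63 nt exon of the kinase Camk2g (chromosome 14, 20757666 to 20757728) rose from 0.00978 (0.0038 to 0.025) to 0.416 (0.368 to 0.466). The 21 nt exon of the muscle transcription factor Mef2d (chromosome 3, 88161781 to 88161801) rose from 0.0636 (0.0174 to 0.206) to 0.589 (0.448 to 0.716). A 40 nt exon of Rbfox2 fell from 0.923 to 0.570, and a 54 nt exon of Mbnl2 fell from 0.987 to 0.623. Rises were also called in Tbc1d23 (0.0376 to 0.524), Apbb2 (0.134 to 0.562), Scamp5 (0.192 to 0.616), Tmem184b (0.0477 to 0.451) and Dennd1a (0.171 to 0.749). Falls were also called in the glycerol kinase gene Gk (0.787 to 0.236), Ppp1r12b (0.914 to 0.410), Exoc1 (0.928 to 0.518), a 3 nt exon of Clasp1 (1 to 0.603) and Adam15 (0.630 to 0.225).

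Of 23042 exons measured with ponA in MEF, 282 were called in 241 genes, 134 higher and 148 lower. On unnormalised read shares the split was 155 higher and 75 lower, with Fisher's exact test 149 and 137, and among exons of at most 75 nt 64 and 42, so which direction was more frequent depends on the setting. RBFOX target genes had 17 of 168 exons called, 10 higher and 7 lower, against a median of 2 in depth-matched random lists, including Plod2 (0.190 to 0.590). MBNL target genes had 19 of 236, 8 higher and 11 lower, including Mbnl1 (0.951 to 0.617 for a 95 nt exon). Splicing regulators had 8 of 204, all 8 lower, in 4 of 46 measured genes, among them Tia1 (0.629 to 0.379). Of these regulator exons, 3 remained when only exons with an uninduced PSI under 0.95 were counted. Cytoskeleton and adhesion genes had 24 of 333, 16 higher and 8 lower, including Dst (0.0235 to 0.391). Muscle genes had 4 of 53, all 4 higher, including Tpm1 (0.252 to 0.454). Genes with epithelial or mesenchymal splicing had 6 of 104, 2 higher and 4 lower, including Map3k7 (0.482 to 0.198). Transcription and chromatin genes had 7 of 206, 4 higher and 3 lower. Membrane traffic genes had 5 of 177, 1 higher and 4 lower, inside the range of random lists. With inflation removed 99 exons were called, and Mef2d, Dennd1a, Gk, Ppp1r12b, Adam15 and 7 others of the 20 largest changes no longer passed. With Fisher's exact test Magi1 and Actn4 failed. Among exons whose mean PSI over the uninduced and ponA libraries was at least 0.95, skipping reads were 0.303% of reads with ponA and 0.184% without it.

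Both drugs together in HEK gave the most calls, with large changes in several exons that a single drug had also moved. The 43 nt exon of the kinase CAMKK2 (chromosome 12, 121244573 to 121244615) rose from 0.0146 (0.00256 to 0.0784) to 0.920 (0.753 to 0.977). ARFGAP2 rose to 0.907, MICAL3 to 0.95, THOC5 to 0.854, MDM1 to 0.940, ARAP1 to 0.823 and AFDN to 0.920. RUBCN rose from 0.131 to 0.855, and VPS39, a tethering factor of lysosomes, rose from 0 to 0.698. ARHGAP4 fell from 1 to 0.0896, FAM122B to 0.0813, SYNE1 to 0.109 and TTC28 to 0.159. The 38 nt exon of the polarity gene SCRIB fell from 0.928 to 0.240, and a 1046 nt exon of the sphingosine kinase SPHK2 fell from 0.916 to 0.230. Of 43818 exons measured, 1393 were called in 1072 genes, 452 higher and 941 lower, against 453 and 573 on unnormalised read shares and 158 and 126 among exons of at most 75 nt. MBNL target genes had 41 of 316 exons called, 24 higher and 17 lower, and RBFOX target genes had 31 of 287, 17 higher and 14 lower, against random medians of 10 and 9. Cytoskeleton and adhesion genes had 49 of 451 (32 higher), genes with epithelial or mesenchymal splicing 25 of 170 (9 higher) and membrane traffic genes 20 of 311 (9 higher). Transcription and chromatin genes had 20 of 328 (11 higher) and muscle genes 8 of 71 (4 higher). Splicing regulators had 11 of 318 (2 higher), inside the range of random lists, with a 40 nt exon of RBFOX2 falling from 0.878 to 0.308. With inflation removed 407 exons were called, and AGAP5, ELOA-AS1, B3GALNT1 and MAPK12 no longer passed. AGAP5 has near-identical copies, so its fall from 1 to 0.183 is uncertain.

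Both drugs together in MEF called 399 of 22855 measured exons in 336 genes, 225 higher and 174 lower, against 242 and 109 on unnormalised read shares. Baz2b rose from 0.0755 (0.0206 to 0.241) to 0.901 (0.748 to 0.965), Tead1 rose to 0.809, Inf2 to 0.870, Numa1 to 0.778 and Mta1 to 0.943. The 130 nt exon of Itga6, a laminin receptor subunit (chromosome 2, 71853534 to 71853663), rose from 0.0199 to 0.759. Add3 fell to 0.272, Numb to 0.182, Slc25a3 to 0.357 and Fryl to 0.0951. The 54 nt exon of Mbnl2 (chromosome 14, 120395712 to 120395765) fell from 0.987 (0.970 to 0.994) to 0.408 (0.357 to 0.461). MBNL target genes had 28 of 245 exons called, 15 higher and 13 lower, and RBFOX target genes had 25 of 190, 14 higher and 11 lower, against random medians of 4 and 3. Cytoskeleton and adhesion genes had 37 of 337 (24 higher), transcription and chromatin genes 15 of 198 (10 higher) and membrane traffic genes 12 of 183 (6 higher). Genes with epithelial or mesenchymal splicing had 9 of 106 (4 higher), splicing regulators 8 of 192 (2 higher) and muscle genes 6 of 56 (3 higher). Tpm1 fell from 0.507 to 0.0813 and Myl6 rose from 0.190 to 0.556. With inflation removed 199 exons were called, and Arhgap17 and Sorbs2 no longer passed. Skipping reads of exons whose mean PSI over these 2 libraries was at least 0.95 were 0.284% of reads with both drugs and 0.189% in the uninduced library.

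Exons called with dox alone and with ponA alone mostly moved the same way. In HEK, AFDN was at 0.218 uninduced, 0.891 with dox, 0.754 with ponA and 0.920 with both. KIF13A was at 0.508, 0.955, 0.958 and 1. ITGA7 (120 nt) was at 0.954, 0.483, 0.476 and 0.536, and RAI2 at 0.0750, 0.544, 0.537 and 0.507. In MEF, Scamp5 was at 0.192, 0.618, 0.616 and 0.632, Exoc1 at 0.928, 0.229, 0.518 and 0.277, and Adam15 at 0.630, 0.134, 0.225 and 0.0937. Opposite movements in HEK were called in LSM14B (0.612 uninduced, 0.261 with dox, 0.848 with ponA, 0.344 with both), ENAH (0.760, 0.187, 0.943, 0.198), GOLIM4 (0.697, 0.329, 0.874, 0.698), FNIP1 (0.220, 0.0485, 0.664, 0.180), FNIP2 (0.205, 0.0419, 0.645, 0.0785) and PPHLN1 (0.552, 0.739, 0.318, 0.723). In MEF they were called in a 36 nt exon of Mbnl1 (0.626, 0.850, 0.345, 0.790) and a 12 nt exon of Dnm2 (0.269, 0.514, 0.106, 0.266). Reads at this Mbnl1 exon were 205 uninduced, 562 with dox, 153 with ponA and 447 with both, so transgene reads can hold part of its rise with dox.

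**Figure D2:**
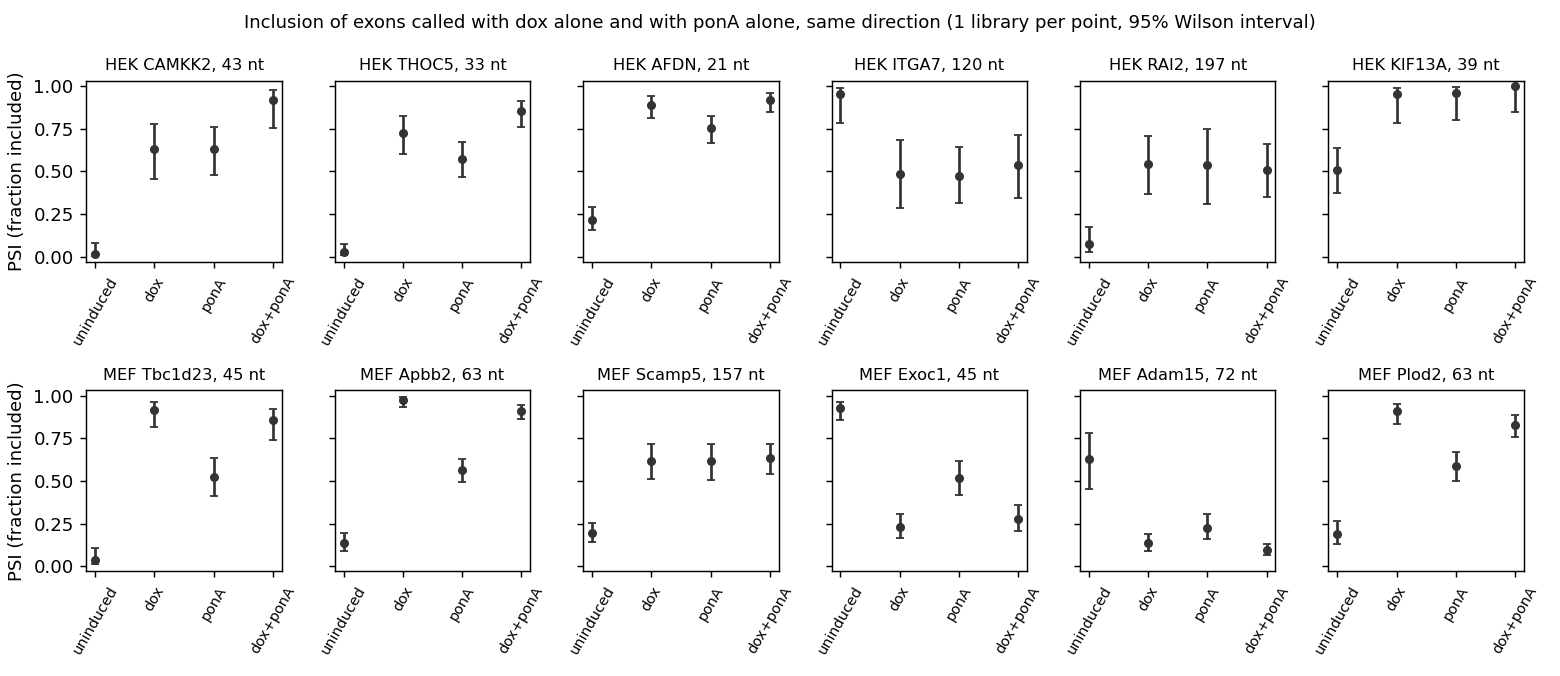
PSI of the 6 exons per line with the largest smaller-of-both effect among those called with dox alone and with ponA alone in the same direction, in each of the 4 libraries of the line. Points are single libraries and bars are 95% Wilson intervals, and HEK KIF13A sits at 0.955 with dox, 0.958 with ponA and 1 with both.

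Among 33453 HEK exons measured in the uninduced, dox and ponA libraries, 606 were called with dox and 229 with ponA. Both calls fell on 61 exons, 53 in the same direction and 8 in opposite directions. Independent lists would share 1.95 in the same direction and 2.20 in opposite directions. Among 16514 MEF exons, 234 were called with dox, 237 with ponA and 59 with both, 57 in the same direction and 2 in opposite directions. Independent lists would share 1.70 and 1.66. Simulated unchanged libraries against the same uninduced library had a median of 4 dox and 1 ponA calls in HEK and 1 and 2 in MEF, too few for their overlap, a median of 0, to serve as a comparison. Across exons, the dox and ponA differences correlated at 0.391 in HEK, where simulated unchanged libraries gave 0.456, and at 0.424 in MEF, where they gave 0.502. Their covariance was higher than simulated, at 0.00169 against 0.00104 in HEK and 0.00165 against 0.000863 in MEF. The simulated libraries hold counting noise only, so neither comparison shows how much of the agreement comes from the shared control. Exons are not independent replicates. Only 1 uninduced library per line was used, so part of the excess overlap, and of its agreement in direction, may come from the shared control. The values for independent lists also take every measured exon as equally likely to be called. Of 40632 exons measured with dox in HEK, 24810 had a mean PSI of at least 0.95 over the 2 libraries. Lists drawn mostly from the other exons would share more than these values, so the excess overlap may come in part from this too. Of exons measured in all 4 libraries, 515 of the 1020 called with both drugs in HEK were called with neither drug alone, and 100 of 371 in MEF. Such exons may have missed a cutoff with a single drug, so these counts do not show regulation by both drugs only. In HEK, 315 of the 515 were lower, 204 of them from near full inclusion. The HEK dox library also had fewer reads per exon, at 0.749 times the uninduced ones against 0.844 with both drugs, and fewer MBNL1 reads.

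The effect of dox was next compared without and with ponA, on exons called with dox and measured in all 4 libraries. Where both drugs moved an exon the same way, dox added less when ponA was present. In MEF, Scamp5 rose by 0.426 with dox alone, while its PSI was 0.616 with ponA and 0.632 with both. In HEK, THOC5 was at 0.0309 uninduced, 0.725 with dox, 0.573 with ponA and 0.854 with both. Over 51 such HEK exons the median dox effect was 0.373 alone and 0.0952 with ponA, a ratio of 0.255 (95% interval over exons 0.203 to 0.456). Simulations with effects that add on the logit scale gave 0.788 to 1.2. Over 57 MEF exons the ratio was 0.423 (0.350 to 0.526), with 0.939 to 1.31 simulated. The simulations called exons with Fisher's exact test, and with that test the observed ratios were 0.423 over 46 HEK exons and 0.443 over 63 MEF exons. Simulated counts hold counting noise only, so their ranges leave out differences between library preparations. The joint effect was 0.626 times the sum of the single effects in HEK and 0.637 times in MEF, with 0.948 to 1.20 and 1.01 to 1.26 simulated. These intervals are over exons, which are not replicates.

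The size of this ratio depended on how exons were chosen in HEK. Chosen and measured on separate parts of the reads, the same-direction exons gave 0.474 (0.255 to 0.815) in HEK and 0.476 (0.371 to 0.582) in MEF, a split that removes counting error only, since the parts come from the same libraries. Chosen by their dox effect in the presence of ponA, they gave 0.725 (0.493 to 1.09, 17 exons) in HEK and 0.446 (0.389 to 0.591, 33 exons) in MEF. Over all exons called with dox, the ratio was 0.565 (0.511 to 0.633) in 233 MEF exons, and 0.588 in the 174 that were not called with ponA. Where MEF exons were chosen with ponA present, 156 gave 0.795 (0.696 to 0.866), so the size of the MEF value over all exons also depended on the choice. Over all 595 HEK exons it was 0.782 (0.704 to 0.835), but 1.01 on separate parts of the reads and 1.75 where exons were chosen with ponA present, so the direction of this HEK value turned with the choice of exons. The 536 HEK exons not called with ponA gave 0.815, and 0.912 with Fisher's exact test, with 0.838 to 0.936 simulated. The exons moved in opposite ways gave 1.65 (0.742 to 3.07) in 8 HEK exons and 1.29 in 2 MEF exons. Their joint effect over the sum of single effects was 4.04 in HEK and 6.32 in MEF. Both ratios divide by a sum near 0, a median of 0.0368 in HEK and 0.0128 in MEF, and changed sign between settings, so they carry no direction.

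**Figure D3:**
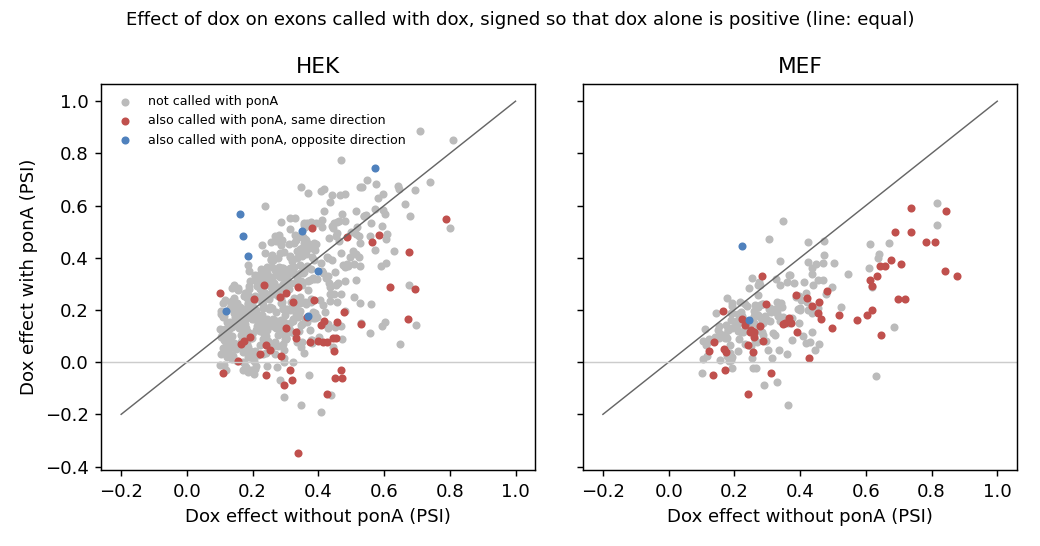
Effect of dox on PSI without ponA (horizontal) and with ponA (vertical) for exons called with dox, signed so that the effect of dox alone is positive, with a line of equality. Same-direction exons (red) lie mostly below the line, with median effects of 0.373 and 0.0952 in HEK and 0.426 and 0.180 in MEF.

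Human and mouse exons of equal length in genes of the same symbol mostly moved alike. The 21 nt exon of AFDN rose with dox from 0.218 to 0.891 in HEK and from 0.00746 to 0.665 in MEF. The 12 nt exon of TEAD1 rose from 0.194 to 0.795 and from 0.00895 to 0.747. A 69 nt exon of SYNE1 rose from 0.364 to 0.938 and from 0.0231 to 0.693, NUMA1 from 0.282 to 0.808 and from 0.0192 to 0.864, and INF2 from 0.520 to 1 and from 0.0923 to 0.874. The 6 nt exon of the clathrin adaptor AP2M1 fell from 0.825 to 0.397 and from 0.961 to 0.565. With ponA, CAMK2G rose from 0.0401 to 0.440 in HEK and from 0.00978 to 0.416 in MEF, MAST2 from 0.121 to 0.761 and from 0.0376 to 0.429, and CLSTN1 from 0.205 to 0.683 and from 0.157 to 0.434. EXOC1 fell from 0.464 to 0.179 and from 0.928 to 0.518, and PBRM1 from 0.828 to 0.347 and from 0.641 to 0.376.

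Of 5728 matched exons measured with dox, 179 were called in HEK, 119 in MEF and 48 in both, where independent lists would share 3.72 (odds ratio 28.3). The direction was the same in 45 of 48 (93.8%, 95% exact interval 82.8 to 98.7). The 45 include the 54 nt exon of MBNL1 itself, where transgene reads can lower PSI in both lines. Over all exons called in a line the share was lower: 132 of the 179 HEK calls (73.7%) had the same sign in MEF, and 101 of the 119 MEF calls (84.9%) in HEK. With ponA, 21 of 6507 were called in both against 2.08 for independent lists (odds ratio 14.6), 20 of them in the same direction, while 82 of the 102 HEK calls (80.4%) and 96 of the 133 MEF calls (72.2%) had the same sign in the other line. With both drugs, 72 of 6830 were called in both against 9.28 (odds ratio 14.8), 67 of them in the same direction, with the same sign in 76.0% of HEK calls and 78.5% of MEF calls. The lines share no library. Exons are not replicates, so no p-value is given. The values for independent lists and the odds ratios take all matched exons as equally likely to be called, whatever their PSI. Exons alternatively spliced in both species can therefore raise the shared count. Requiring equal flanking exons as well left 15, 7 and 21 exons called in both.

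**Figure D4:**
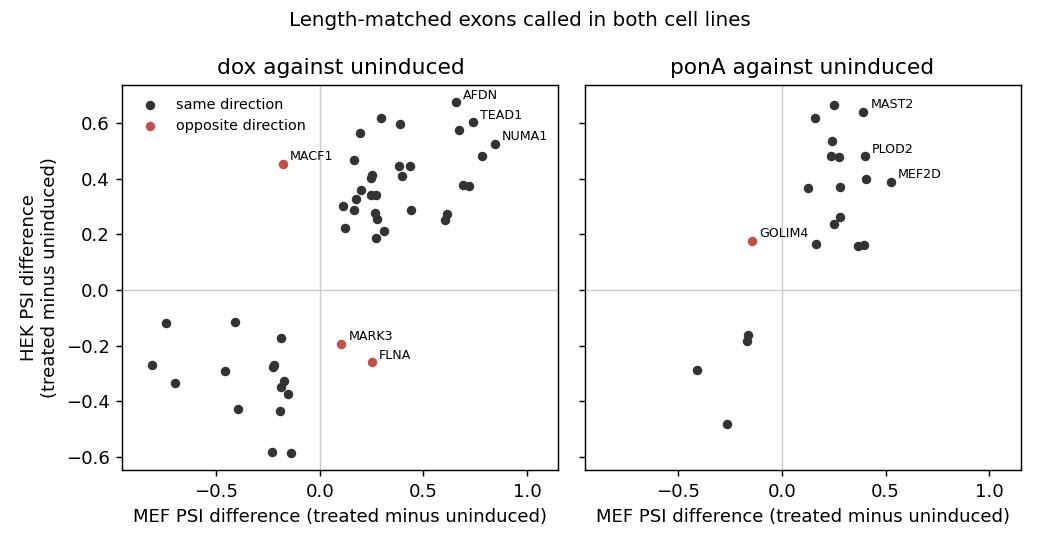
Change in PSI with dox (left) and ponA (right) for length-matched exons called in both lines, MEF on the horizontal and HEK on the vertical axis. Of these exons, 45 of 48 with dox and 20 of 21 with ponA lie in the quadrants of equal direction.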

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

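Several tests were chosen only after the results they bear on were seen. These were the tests of short exons, of ponA in HEK, of MBNL1 read levels and of exons chosen by the dox effect with ponA. So were those of depth in MEF and of what equal depth leaves in HEK. The criteria for short exons and for ponA in HEK were then changed with their values known, which turned both explanations from excluded to open, and the test on separate parts of the reads was corrected after its first values were seen.

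Length-matched exons called in both lines moved in opposite directions in 9 cases, which flagged them. The difference between the lines was not tested, since these exons were picked for it and each group has 1 library. With dox, the change in HEK minus that in MEF was -0.511 for FLNA (24 nt), 0.631 for MACF1 (18 nt) and -0.297 for MARK3 (27 nt). With ponA it was 0.322 for GOLIM4 (84 nt). With both drugs it was 0.831 for WDFY3, -0.621 for TCF3, -0.552 for FLNA, -0.392 for MFF and -0.272 for MDM4. TCF3 has mutually exclusive exons, so its match between species is uncertain.

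The effect of dox was smaller with ponA than without. The ratio was 0.255 in HEK same-direction exons, 0.423 in MEF same-direction exons and 0.565 in all MEF exons called with dox. Called with Fisher's exact test, as in the simulations, these ratios were 0.423, 0.443 and 0.590. Each lay below the range simulated without interaction, but the simulations hold counting noise only and no differences between library preparations. Limits of the PSI scale alone are argued against, since the logit ratio was 0.275 (0.184 to 0.418) in HEK and 0.294 (0.242 to 0.367) in MEF. The 0.5 reads added cap the logit of exons near 0 or 1, so this ratio is not free of limits. The simulations without interaction, whose PSI has the same floor and ceiling, still gave higher ratios for same-direction exons. Shrinkage of exons picked for a large effect stays open for the same-direction exons. Chosen by the dox effect with ponA, they gave 0.446 (0.389 to 0.591) in MEF and 0.725 (0.493 to 1.09) in HEK. Their ponA call still used the ponA and uninduced libraries, whose deviations enter this ratio. Separate parts of the reads (0.474 in HEK, 0.476 in MEF), the test used first, share the deviations of their libraries. With no ponA call required, exons chosen by the dox effect with ponA gave 0.795 (0.696 to 0.866) in MEF and 1.75 in HEK. This choice favours the effect with ponA, so the MEF value argues against shrinkage as the whole cause over all MEF exons. Shrinkage may still account for part of the 0.565. Fewer MBNL1 transcripts with both drugs are argued against in HEK, where MBNL1 reads were 1.35 times (1.33 to 1.38, counting error only) those with dox alone, and stay open in MEF at 0.890 (0.832 to 0.951), while MBNL1 protein was not measured. A shared action of MBNL1 and RBFOX1 may contribute in exons that both moved. HEK exons not called with ponA kept more of the effect, at 0.815 (0.912 with Fisher's exact test, 0.838 to 0.936 simulated). The 174 MEF exons not called with ponA gave 0.588 (0.640 with Fisher's exact test, 0.876 to 1.0 simulated). Exons not called can still be moved by ponA, and the median ponA effect of these MEF exons was 0.0335 in the direction of dox. They therefore cannot decide on a shared action, which stays open. A difference between single library preparations cannot be told apart from the drugs.

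In HEK more exons were called lower than higher with dox and with both drugs, mostly from near full inclusion. At equal reads per exon the ratio of lower to higher calls with Fisher's exact test was 1.32 (1.09 to 1.61) with dox, from 1.73, and 1.49 (1.3 to 1.72) with both, from 1.95, so lower depth of the treated libraries may account for the part removed, and is argued against for the part left. A ceiling that lets noise show only falls was examined by mirrored counts. Falls from near full inclusion were 5.57 times rises to it with dox (301 and 54) and 10.1 times with both drugs (688 and 68). These counts were not taken at equal reads per exon, where treated libraries held 0.749 (dox) and 0.844 (both) times the uninduced reads. They therefore cannot separate a ceiling from lower depth, and a ceiling stays open. Reads inside long exons stay open: in exons of at most 75 nt lower calls no longer outnumbered higher ones, at 0.804 (0.584 to 1.1) with dox and 0.797 (0.626 to 1.01) with both, although their mirrored ratios were 3.20 and 4.93. No biological explanation was tested.

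In MEF, nearly fully included exons had more skipping reads with ponA and with both drugs. Greater depth is argued against, since skipping rates were 1.65 (1.6 to 1.70) and 1.5 (1.46 to 1.55) times the uninduced ones at 0.985 and 1.06 times the reads per exon, and a few genes by 63.5% and 61.3% of exons having the higher rate in the treated library. PonA acting alike in any line stays open, because the HEK libraries disagree, at 1.07 (1.05 to 1.09) with ponA, 1.40 (1.37 to 1.44) with both drugs and 1.20 with dox alone, while MEF with dox alone was at 1.01 (0.984 to 1.04). RBFOX1 activity in MEF and a difference in library preparation may each contribute and cannot be told apart with 1 library per group.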

How the results depend on the processing

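No paired analysis was possible because each group has 1 sample. Motif counts beside exons were not run, since no genome was used here. The limit on exon length, the limit on uninduced PSI and the separate parts of the reads were chosen after seeing the data. Where 1 exon was left no value is given. The cause was not tested unless fewer exons or reads entering the count shows it. With reads cut to equal numbers per exon, calls by Fisher's exact test went from 396 lower and 229 higher to 242.5 and 183 (HEK dox, medians) and from 795 and 408 to 500 and 335 (HEK both), so depth limits the counts. In simulations, 14% of true differences of 0.1, which the 0.1 cutoff itself removes in part, and 52% of those of 0.2 were recovered. Of the 120 exons named by size, 8 failed with Fisher's exact test, 6 at an FDR under 0.01 in the authors' deposited table, 35 with inflation removed and 1 on unnormalised read shares, none reversed, and 57 had fewer than 50 reads. Of 48 gene list counts, 31 were more than 1.5 times lower with inflation removed, 11 with a PSI difference of at least 0.2, 7 at an uninduced PSI under 0.95, and 5 each with at least 50 reads or an FDR under 0.01 in the authors' deposited table, and 5 were higher with no read minimum.

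Counts called are for HEK ponA, dox and both, then MEF ponA, dox and both. With no read minimum they were 900, 1532, 2432, 461, 410 and 606, with inflation removed 77, 197, 407, 99, 140 and 199, and among exons of at most 75 nt 104, 166, 284, 106, 112 and 160. In these short exons the more frequent direction turned in HEK dox (92 higher, 74 lower), HEK both (158 and 126) and MEF ponA (64 and 42). An FDR under 0.01 in the authors' deposited table left 145 (HEK ponA) and 482 (HEK dox). An uninduced PSI under 0.95 left 430 (HEK dox, 266 higher and 164 lower), 705 (HEK both, 452 and 253) and 172 (MEF ponA, 134 and 38), where it turned too by construction. MEF ponA also turned with Fisher's exact test (149 and 137), an FDR under 0.01 in the authors' deposited table (109 and 89), a difference of 0.2 (73 and 70) and inflation removed (61 and 38).

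With a PSI difference of at least 0.2, 143 (MEF ponA) and 254 (MEF both) were called, single drugs shared 40 (HEK) and 36 (MEF), lines shared 31 (dox) and 13 (ponA), and the HEK dox effect retained with ponA was 0.860. With at least 50 reads it was 0.913, and 0.485 in same-direction exons, and lines shared 31 with dox. With equal flanking lengths they shared 15 (dox), 7 (ponA) and 21 (both). The retained HEK effect was 0.863 with Fisher's exact test, 0.698 on the logit scale and 0.699 at an uninduced PSI of 0.2 to 0.8. On separate parts of the reads it was 1.01, and 0.474 in same-direction exons. Chosen with ponA present, HEK exons gave 1.75 (all), 0.725 (same direction) and 11.6 (opposite), and MEF exons 0.795 (all) and 14.6 (opposite).

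On the logit scale the retained MEF effect was 0.493 (all) and 0.294 (same direction), and the joint effect over the sum of single effects was 0.541 in same-direction MEF exons. For opposite-direction exons that sum is near 0 and the ratio cannot be interpreted: it was 9.73 (HEK) and -5263 (MEF) on the logit scale, -4.40 (HEK) and -5.99 (MEF) with Fisher's exact test, and -1.81 (HEK) and -6.89 (MEF) on unnormalised read shares.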

Other observations

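The comparisons of exon length and of the uninduced state were chosen after the data were seen.

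Exon lengths were a multiple of 3 nt in 65.3% of exons called with ponA in HEK and 38.8% of uncalled ones, in 52.4% and 38.5% with dox in HEK, and in 66.3% and 41.4% with ponA in MEF. Exons called with both drugs and with neither alone were 315 lower and 200 higher in HEK, and 50 lower and 50 higher in MEF. Of the lower ones, 204 in HEK and 21 in MEF started near full inclusion.

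Among exons with an uninduced PSI of 0.05 to 0.95, those of at most 27 nt were called in 21 of 153 with dox in HEK (odds ratio against longer exons 4.65, 2.75 to 7.51) and 17 of 164 with ponA in HEK (9.23, 5.09 to 15.8). In MEF they were called in 18 of 122 with dox (5.29, 2.93 to 9.05) and 12 of 123 with ponA (5.48, 2.65 to 10.4). Exons are not replicates.

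Of the length-matched exons that dox moved the same way in both lines, 38 of 45 (84.4%, 70.5 to 93.5) lay further in that direction in uninduced HEK than in uninduced MEF. For ponA the share was 13 of 20 (65.0%, 40.8 to 84.6).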
